A study of Homo sapiens with 8 samples.

How the data were processed

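RNA sequencing was analysed from 8 tumours of 1 breast cancer patient-derived xenograft, a human tumour passaged in mice. Per the labels' protocols, tumour cells were implanted in Rag2-/-γc-/- mice, which lack mature lymphocytes. The mice received a control human antibody (4 tumours) or cirmtuzumab at 10 mg/kg (4 tumours). Cirmtuzumab is a humanised antibody against the receptor ROR1. Libraries were made with a stranded, poly(A)-based mRNA kit, per the labels' protocols.

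The authors deposited 1 table of genes by 8 libraries. Its deposited values are log2 CPM. The values themselves show how they were scaled, since 0.5 had been added to each count and the sum divided by a scaled library size. The lowest value of each library is then a count of 0, which allowed each expected count to be recovered. Recovered values under 10000 lay on a grid of 0.01 in 100% of cases (tolerance 0.0001), as RSEM expected counts do. Cutadapt, STAR, RSEM 1.3.0, DESeq2 and limma are named by the submitters' processing notes, without a role or an order. Aligner settings, genome build, annotation, the filter on low genes and any removal of mouse reads are not given in the sources used here. Recovered totals were 33.8, 41.4, 43.8 and 36.5 M expected counts in the control libraries and 38.3, 40.6, 21.4 and 21.9 M in the cirmtuzumab libraries.

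The deposited gene symbols were displaced against the Ensembl identifiers from row 7248 of the table on. Before that row 7106 of 7233 named rows (98.2%) carried the symbol of their own identifier. From it on none of 6331 did, and 6112 carried the symbol of another listed row, most often 2 rows away. The values went with the identifiers. From that row on, 23 cytosolic ribosomal protein genes had a median of 9.72 log2 CPM when found by identifier and 5.23 when found by deposited symbol. Another 23 deposited symbols had been turned into dates. Symbols were therefore taken from the identifiers, of which 14917 matched a table of current symbols and 15001 matched that table or GENCODE 29. Deposited symbols were used only where neither matched, before row 7248. Positions, transcript lengths and GC content came from GENCODE 29 on GRCh38, which need not be the authors' annotation.

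The table's column names showed the group of each library but not which labelled replicate it was, since the numbers in them are not those of the labels. Libraries are therefore called A to D within a group, in the order of the table, and the letters pair nothing. No 2 libraries held identical values. The labels do not say whether the 4 tumours of a group were grown as 1 batch.

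Each gene was tested with limma 3.58.1 in R 4.3.3 (linear model, moderated test with a mean-variance trend, Benjamini-Hochberg adjusted p under 0.05). All 8 libraries entered the fit, with the group as the only term. XIST and Y-linked genes were left out of every step. Before the data were examined, 33 gene lists were fixed: pathways named in work on ROR1, general tumour programmes, signs of RNA quality, and markers of other cell types. The 29 lists with at least 5 measured members were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 29 lists. Camera compares a list with all other genes. Camera with an estimated correlation, camera on ranks and fry were alternatives. ROR1, WNT5A and the list scores were also tested by exact two-sided permutation over the 70 splits of the libraries, whose smallest p is 0.0286. A list score is the mean over the members of log2 CPM minus the control mean.

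Genes were named by a rule fixed before the data were examined. It took ROR1, ROR2 and WNT5A. It then took genes past the threshold whose groups did not overlap and whose mean lay above the lowest 25% of genes, up to 10 per direction. Where too few passed, each direction was filled to 5 with the smallest unadjusted p among genes meeting the other conditions, and such genes are named as not past the threshold. Clone-based symbols and pseudogenes were passed over. Within each list it took the 3 members with the smallest unadjusted p. GATD3, GATD3B and AC092849.2 fall outside the rule and were chosen after their values were seen.

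The model was tested on simulated expected counts with 200 genes changed. With the spread of the 7 similar libraries it recovered 56% of genes changed 1.5-fold, 98% at 2-fold, and 100% at 4-fold and 8-fold, with 14 unchanged genes called. With the deviations of the outlying library described in the report added, it recovered 22%, 82%, 92% and 98% at those sizes, with 0 unchanged genes called. The adjusted p depends on how many genes change, so these shares apply to 200 changed genes and not to data with fewer. Camera called the 1 changed list in both simulations and 0 other lists. The counts were drawn independently for each gene, so list members lacked the correlation of real lists. That correlation was estimated at 0.024 (Hippo components) to 0.489 (oxidative phosphorylation) in the lists that passed. The simulations therefore do not show how often camera calls unchanged lists in these data.

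Alternatives fixed before the data were examined were a filter on the lowest 25% of genes, quantile normalization, centring on the median of the more highly expressed genes, other variance models, weights per library, other set tests, an adjusted p under 0.1, and leaving out each library. Added after the data were seen were voom weights from the recovered expected counts, adjustment for transcript length and GC content, the deposited symbols, the sum of GATD3 and GATD3B, the fibroblast mean as a covariate, a block on the numbers in the column names, and the estimated correlation without the outlying library. Library weights, voom and the adjustments also used limma. Figures were drawn with matplotlib 3.10.9.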

Results

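RNA sequencing compared 4 xenograft tumours from mice given a control antibody with 4 tumours from mice given cirmtuzumab. All tumours came from the same breast cancer xenograft. The comparison asks what an antibody against ROR1, a cell surface receptor for Wnt5a that is studied as a marker of breast cancer stem cells, does to the tumour's transcripts. Expression is given as log2 CPM, as scaled by the authors. Library totals ran from 21.4 M to 43.8 M expected counts. The 2 shallowest libraries, at 21.4 M and 21.9 M, were both from the cirmtuzumab group. Differences are cirmtuzumab minus control on the log2 scale, with the standard error (SE) of limma and n = 4 per group.

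Among single genes, only GATD3 passed the threshold in the limma model without library weights, over all 8 libraries. It was higher with cirmtuzumab by 1.78 log2 units (SE 0.17). The call ended when any 1 of 7 similar libraries was left out, and when GATD3 was summed with its near-identical copy GATD3B. ROR1 itself did not pass. Among gene lists, DNA replication, oxidative phosphorylation, ribosomal protein, heat shock, cholesterol synthesis and histone genes were higher with cirmtuzumab, by medians of 0.11 to 0.30. The heat shock and histone lists had been fixed as signs of RNA quality, and they were higher beside the other 4 lists. YAP/TAZ targets, mesenchymal genes, fibroblast markers, hypoxia genes and Hippo components were lower, by medians of -0.44 to -0.08. These list calls came from camera with a preset correlation and none held with an estimated one (lowest adjusted p = 0.594 with an estimated correlation).

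One cirmtuzumab library stood apart from the other 7. Its Pearson correlations across genes with the other libraries lay between 0.872 and 0.881, against 0.955 to 0.984 among the other 7. The first principal component, 64.3% of the variance, separated it from the rest. In this library 820 genes lay over 2 log2 units below the mean of the others and 169 lay as far above. No other library had more than 86 such genes in both directions together. Its depth of 38.3 M was within the range of the others. Results are given for all 8 libraries, as designed, and the values without this library are added for the targets and for several lists and genes.

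**Figure D1:**
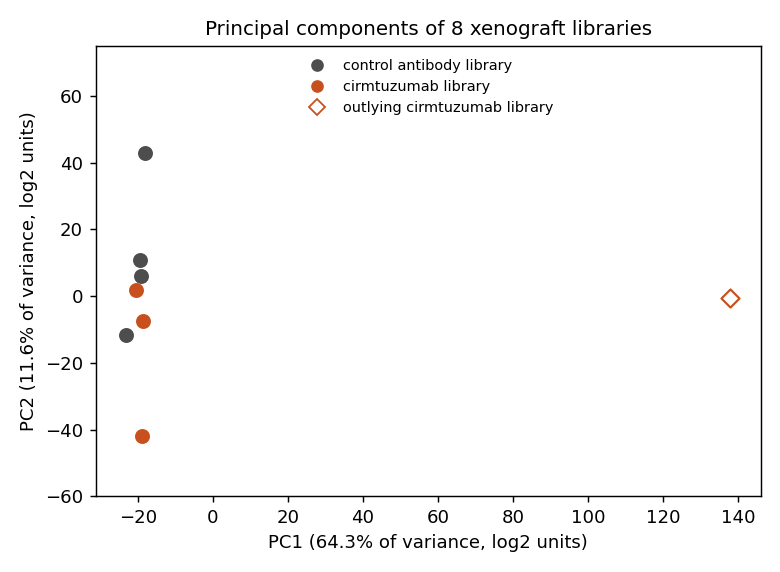
First and second principal components of log2 CPM in the 8 libraries, one point per library. The outlying cirmtuzumab library sits at 138 on PC1, and the other 7 sit between -23.2 and -18.1.

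ROR1, the target of the antibody, was not detectably changed. ROR1 (ENSG00000185483; chromosome 1, 63774022 to 64181498, GRCh38) had 4.49 ± 0.21 log2 CPM in control tumours and 3.92 ± 0.98 in cirmtuzumab tumours (SD, n = 4 each). The difference was -0.57 (SE 0.42), with an exact permutation p of 0.171 over 70 splits. Most of it came from the outlying library, where ROR1 was at 2.47. Without that library the difference was -0.09 (SE 0.15). WNT5A, a ligand of ROR1, had 2.70 ± 0.09 in control and 2.91 ± 0.45 in cirmtuzumab tumours, a difference of 0.21 (SE 0.22; exact permutation p = 0.457), and of 0.02 without the outlying library. ROR2, the related receptor, was not among the genes listed.

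One gene passed the threshold across all genes. GATD3 (ENSG00000160221; chromosome 21, 44133605 to 44210114, GRCh38), a gene for a mitochondrial protein, rose by 1.78 (SE 0.17; limma adjusted p = 0.0456), from 1.45 ± 0.22 to 3.24 ± 0.17 log2 CPM. It was higher in 4 of 4 cirmtuzumab libraries than in any control. GATD3 shares reads with a near-identical copy, GATD3B (chromosome 21, 5079294 to 5128425), at 6.05 ± 0.21 in control and 6.30 ± 0.21 in cirmtuzumab tumours. GATD3 took 3.94% of the expected counts of both copies in control tumours and 10.8% in cirmtuzumab tumours. Both copies summed differed by 0.35 (SE 0.133, limma adjusted p = 0.753), so the call ended there. A rise of GATD3 alone would move the sum by 0.13, less than that SE. The sum therefore cannot tell a rise of GATD3 from reads moved between the copies. The GATD3 call ended when any 1 of the 7 similar libraries was left out (adjusted p from 0.0924 to 0.36, and from 0.000516 to 0.766 over all alternatives), while its difference stayed between 1.70 and 1.88. GATD3 lies in the lowest 25% of genes by mean and was chosen after its values were seen.

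No gene passed as lower with limma in the model used here, or with voom weights. With weights per library SLC6A6 (-0.72, adjusted p = 0.0195, and from 0.0195 to 0.951 over its alternatives) and AC092849.2 passed as lower. With voom weights and a weight per library AC092849.2 passed as lower and FP565260.2, chosen after its values were seen, as higher. At an unadjusted p under 0.05 there were 302 lower and 419 higher genes, 721 in all, against 755 expected by chance. The next adjusted p after GATD3 was 0.753. The groups did not overlap for 542 genes (3.59%), where chance gives 2.86%. Without the outlying library 1 gene passed as higher, GATD3 (1.85, SE 0.17; adjusted p = 0.0101), and 1 as lower. The lower gene was the antisense transcript AC092849.2 (ENSG00000241357; chromosome 7, 100435257 to 100436510), at 0 expected counts in the other 3 cirmtuzumab libraries. It had between 29.3 and 74.7 expected counts in the controls and 48.7 in the outlying library. The strand setting of the counting is not stated, so reads from the opposite strand are not ruled out there. AC092849.2 was also chosen after its values were seen.

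The genes with the smallest unadjusted p outside the threshold, among those meeting the rule's other conditions, follow, 5 on each side. MRPL57, a mitochondrial ribosomal protein, differed by 0.69 (SE 0.19), CMC1, an assembly factor of cytochrome c oxidase, by 0.51 (SE 0.14), and CHCHD1, another mitochondrial ribosomal protein, by 0.42 (SE 0.10). QPRT, an enzyme of NAD synthesis, differed by 0.49 (SE 0.14). SMN1, which functions in spliceosome assembly, differed by 0.47 (SE 0.12), and it shares reads with its copy SMN2. On the lower side FBN1, the extracellular matrix protein fibrillin-1, differed by -1.20 (SE 0.28). SLC6A6, the taurine transporter, differed by -0.62 (SE 0.11), NXPE3 by -0.48 (SE 0.12), CEP170, a centrosomal protein, by -0.41 (SE 0.09), and DENND2B, a regulator of Rab GTPases, by -0.41 (SE 0.09). The rule took only genes whose 4 cirmtuzumab values lay on 1 side of the 4 control values. That separation is therefore not a finding about these 10 genes. Their adjusted p was 0.753. Without the outlying library SLC6A6 and FBN1 had an adjusted p of 0.21 and the other 8 one of 0.764.

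**Figure D2:**
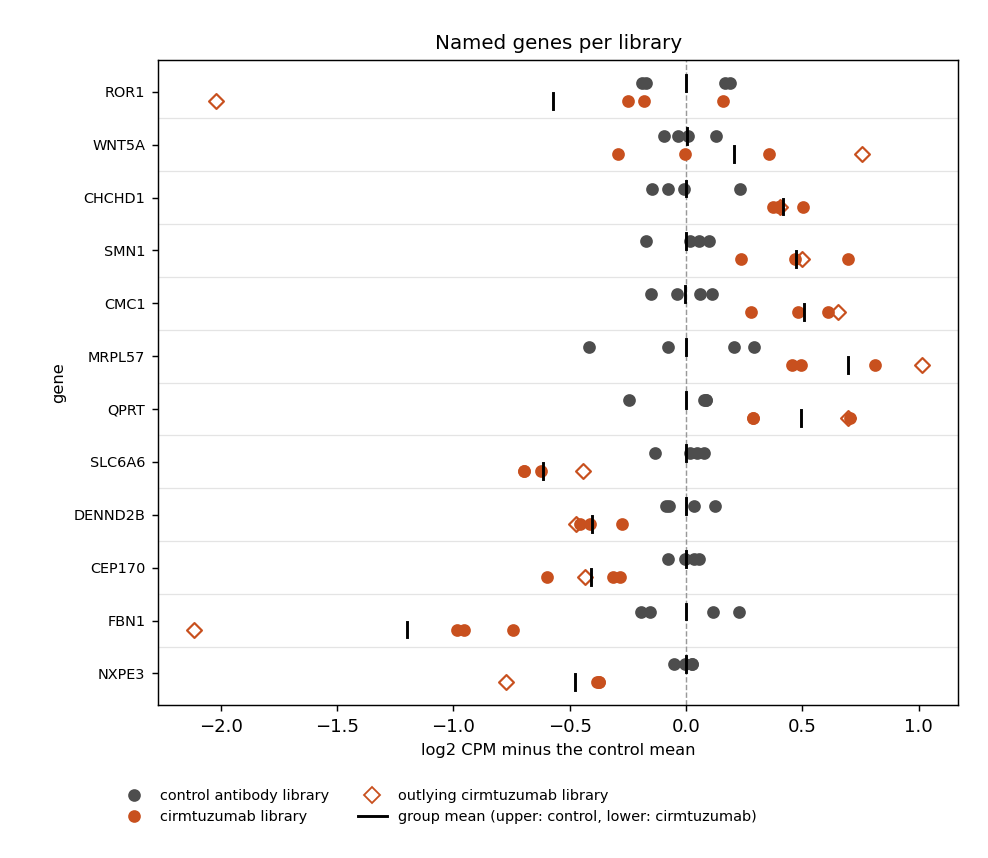
Log2 CPM minus the control mean for ROR1, WNT5A and the 10 genes named by smallest unadjusted p, one point per library, with group means as bars. The 10 genes were taken only where the groups do not overlap, and their differences run from -1.20 (FBN1) to 0.69 (MRPL57). The ROR1 and WNT5A groups overlap.

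Of the 29 gene lists tested, 11 passed the threshold with camera at its preset correlation, 6 as higher and 5 as lower. Other splits of the same 8 libraries into 4 and 4 gave a median of 6 lists and at most 10. None passed with an estimated correlation, where the lowest adjusted p was 0.594, and none with fry, where it was 0.451 for change in one direction and 0.27 for change in either direction. No list score passed its exact permutation test (smallest adjusted p = 0.497). Without the outlying library 12 lists passed, 10 of them shared and all 10 in the same direction, and none passed there with an estimated correlation (lowest adjusted p = 0.601 with an estimated correlation). Within the 11 lists no member passed over all genes. Adjusted over the list alone, 1 fibroblast marker, FBN1, passed as lower, and 0 members of the other 10 lists passed.

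YAP/TAZ target genes, which respond to the Hippo pathway's transcriptional effectors, fell as a list, with 15 of 17 measured members below 0 and a median difference of -0.35 (camera adjusted p = 4.08e-05, and adjusted p = 0.594 with an estimated correlation). AXL, a receptor tyrosine kinase, differed by -0.52 (SE 0.20), DOCK5, an activator of Rac, by -0.41 (SE 0.15), and PTPN14, a phosphatase that restrains YAP, by -0.30 (SE 0.14). The outlying library had a list score of -0.97 and the other 3 cirmtuzumab libraries scores from -0.27 to -0.11, against -0.20 to 0.15 in the controls. Without that library the median was -0.21 with AXL at -0.34, and the list passed at the preset correlation (adjusted p = 0.000187, and from 1.42e-07 to 0.712 over all alternatives) but not with an estimated one (adjusted p = 0.601 with an estimated correlation).

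Hippo pathway components fell by a smaller margin, with 16 of 23 below 0 and a median of -0.08 (camera adjusted p = 0.0385, and adjusted p = 0.594 with an estimated correlation). WWTR1, which encodes TAZ, differed by -0.27 (SE 0.10), the kinase MAP4K4 by -0.18 (SE 0.08), and the cadherin DCHS1 by -0.67 (SE 0.35), or by -0.28 without the outlying library. This call ended without control C, control D, cirmtuzumab B or cirmtuzumab C (adjusted p from 0.0641 to 0.186, and from 0.00607 to 0.712 over all alternatives). It also ended without the mean-variance trend and with voom weights (adjusted p = 0.0596 and 0.0574). After adjustment for transcript length and GC content, which moved the median of all genes from -0.002 to 0.062, its median was 0.01, or -0.05 relative to all genes (adjusted p = 0.558).

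Mesenchymal genes fell with 11 of 15 members below 0 and a median of -0.34 (camera adjusted p = 0.0432, and adjusted p = 0.594 with an estimated correlation). PRRX1, a transcription factor of mesenchymal cells, differed by -0.73 (SE 0.21), LOX, which cross-links collagen, by -0.43 (SE 0.17), and the repressor ZEB2 by -0.47 (SE 0.31). The call ended without control B, control C, cirmtuzumab C or cirmtuzumab D (adjusted p from 0.0985 to 0.252, and from 0.00436 to 0.712 over all alternatives). Without the outlying library the median was -0.17 and the list passed at the preset correlation (adjusted p = 0.00969, and adjusted p = 0.601 with an estimated correlation). The outlying library had a score of -0.52, the lowest of the 8. It did not pass with quantile normalization (median -0.09, adjusted p = 0.07) or weights per library (median -0.17, adjusted p = 0.157), nor with centring, ranks, voom weights or the filter on low genes (adjusted p from 0.0574 to 0.0702).

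Fibroblast markers moved with these lists. They fell with 10 of 12 members below 0 and a median of -0.44 (camera adjusted p = 0.0179, and adjusted p = 0.594 with an estimated correlation). FBN1 is given above, COL5A2, a fibrillar collagen chain, differed by -0.61 (SE 0.36), and POSTN, a matrix protein of fibroblasts, by -0.56 (SE 0.34). The outlying library had a score of -0.97. Without it the median was -0.22 and the list did not pass (adjusted p = 0.0538), nor did it pass without control B (adjusted p = 0.59, and from 0.00068 to 0.712 over all alternatives). The call also ended without the lowest 25% of genes (median -0.19, adjusted p = 0.079) and with weights per library (median -0.09, adjusted p = 0.26). Fibroblasts around a xenograft are mouse cells, and how mouse reads were handled is not given, so these values are of genes counted as human and are not a measured share of fibroblasts. With the fibroblast mean as a covariate the YAP/TAZ targets had a median of -0.12 (adjusted p = 0.366) and the mesenchymal genes one of -0.07 (adjusted p = 0.496).

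Hypoxia response genes also fell, with 20 of 24 members below 0 and a median of -0.17 (camera adjusted p = 0.00635, and adjusted p = 0.687 with an estimated correlation). The glucose transporter SLC2A3 differed by -0.76 (SE 0.32), the glycolytic regulator PFKFB3 by -0.26 (SE 0.13), and the histone demethylase KDM3A by -0.30 (SE 0.15). One cirmtuzumab library, D, had a score of -0.50, and without it the median was -0.05 and the call ended (adjusted p = 0.303) and without control C (adjusted p = 0.252, and from 0.000116 to 0.712 over all alternatives). It also ended with weights per library, at a median of -0.10 (adjusted p = 0.287).

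S phase and DNA replication genes rose, with 29 of 33 members above 0 and a median of 0.23 (camera adjusted p = 1.83e-09, and adjusted p = 0.594 with an estimated correlation). PCNA, the sliding clamp of DNA polymerases, differed by 0.29 (SE 0.10), RRM2, a subunit of ribonucleotide reductase, by 0.37 (SE 0.12), and CDT1, a replication licensing factor, by 0.65 (SE 0.22). In all 3 the groups did not overlap, as in 3.59% of all genes, where chance gives 2.86%. These 3 were taken for the smallest unadjusted p in the list, so that separation is not a finding about them. For CDT1 control A lay at 4.17 log2 CPM, against 5.06 to 5.12 in the other controls. G2 and mitosis genes did not pass, with 19 of 30 above 0 and a median of 0.02 (adjusted p = 0.666). Replication-dependent histone genes, a list fixed as a sign of RNA quality, passed, with 11 of 15 above 0 and a median of 0.30 (camera adjusted p = 0.0242, and adjusted p = 0.602 with an estimated correlation), including H4C8 at 0.48 (SE 0.13) and H1-2 at 0.30 (SE 0.11). The histone call ended without control A, control B, cirmtuzumab C or cirmtuzumab D (adjusted p from 0.0544 to 0.303, and from 3.77e-05 to 0.702 over all alternatives), with a median of 0.16 without cirmtuzumab D. It also ended with voom weights (median 0.29, adjusted p = 0.0552) and after adjustment for transcript length and GC content (median 0.31, or 0.25 relative to all genes, adjusted p = 0.232).

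All 36 nuclear-encoded oxidative phosphorylation genes lay above 0, with a median of 0.20 (camera adjusted p = 3.19e-10, and adjusted p = 0.594 with an estimated correlation). Among them the respiratory chain subunits COX5B, UQCRQ and UQCRFS1 differed by 0.59 (SE 0.21), 0.44 (SE 0.18) and 0.37 (SE 0.15), and without the outlying library by 0.56, 0.29 and 0.22. The 15 mitochondrially encoded genes did not pass, with a median of 0.08 (adjusted p = 0.429). Cytosolic ribosomal proteins rose, with 58 of 61 above 0 and a median of 0.16 (camera adjusted p = 2.86e-08, and adjusted p = 0.602 with an estimated correlation). The median was 0.09 without control B and 0.08 with quantile normalization, and the list passed in both. RPS15, RPS21 and RPS29 differed by 0.59 (SE 0.23), 0.27 (SE 0.11) and 0.28 (SE 0.12). For RPS15 control A lay at 6.43 log2 CPM, against 7.05 to 7.16 in the other controls.

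Heat shock genes, also fixed as a sign of RNA quality, rose, with 14 of 15 above 0 and a median of 0.23 (camera adjusted p = 0.000234, and adjusted p = 0.601 with an estimated correlation). The chaperones HSPE1, HSPH1 and DNAJB1 differed by 0.33 (SE 0.12), 0.31 (SE 0.13) and 0.29 (SE 0.13). Cholesterol synthesis enzymes rose, with 19 of 24 above 0 and a median of 0.11 (camera adjusted p = 0.00289, and adjusted p = 0.601 with an estimated correlation). PMVK, FDPS and MVD, all enzymes of the mevalonate pathway, differed by 0.30 (SE 0.13), 0.25 (SE 0.11) and 0.52 (SE 0.25). For MVD control A lay at 4.67 log2 CPM, against 5.6 to 5.82 in the other controls.

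**Figure D3:**
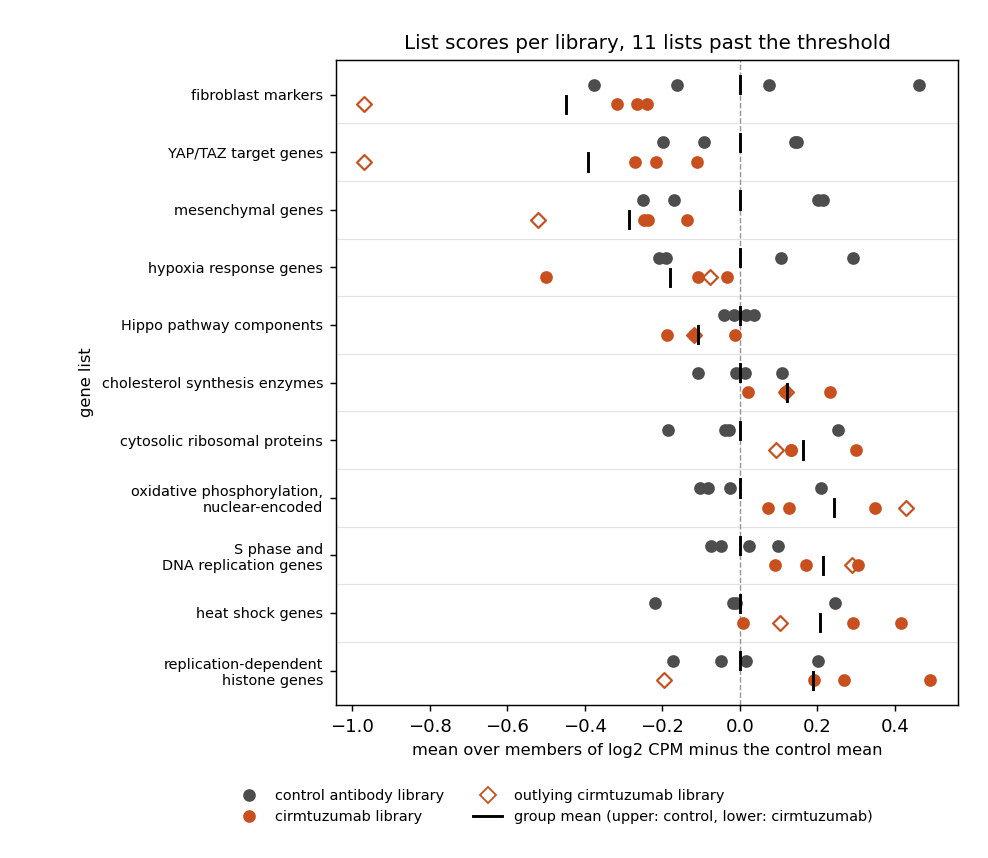
List scores (mean over the members of log2 CPM minus the control mean) for the 11 lists past the threshold, one point per library, with group means as bars. The groups overlap in each of the 11 lists, and the outlying library lies lowest for fibroblast markers and YAP/TAZ targets (-0.97 in both), mesenchymal genes (-0.52) and histone genes (-0.195).

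The lists closest to ROR1 signalling did not pass. Wnt5a/ROR pathway genes had a median of -0.04 (20 measured, adjusted p = 0.732), with WNT5B at -1.14 (SE 0.49), VANGL1 at -0.20 (SE 0.11) and SCRIB at 0.39 (SE 0.28). BMI1 and Polycomb repressive complex 1 genes had a median of 0.01 (20 measured, adjusted p = 0.726), and breast cancer stem cell markers one of 0.04 (15 measured, adjusted p = 0.739). Canonical Wnt targets, at 0.13 (10 measured, adjusted p = 0.271), did not pass either. Without the outlying library the medians of these last 2 lists were -0.06 and 0.06. Simulated data with the deviations of the outlying library had 200 genes changed, none of them among the lowest 25% by mean. There the model recovered 22% of genes changed 1.5-fold and 82% changed 2-fold. The adjusted p depends on how many genes change, so these shares do not give the recovery in the real data. In the real data SLC6A6, with an unadjusted limma p of 0.000284, had an adjusted p of 0.753. Single-gene differences of 1.5-fold and 2-fold could therefore be missed more often than these shares show.

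Markers of cell types other than tumour cells were scarce. The mean scores of 5 such lists were lowest in the outlying library, where 16 of their 27 measured markers lay below each of the other 7 libraries. Another 5 lay above each of them (COL6A3, COL1A2, ENG, EMCN and CD14), with EMCN at 2.43 log2 CPM against 0.50 to 1.26 and CD14 at 2.94 against 0.93 to 1.69. Skeletal muscle markers (5 measured) had a median of -0.49 (adjusted p = 0.371), and one of 0.13 without the outlying library. Endothelial markers (4 measured), macrophage and myeloid markers (4), adipocyte markers (2) and erythroid markers (1, HBB) were too few to test, with medians of -0.54, -0.29, -0.19 and -2.43. The outlying library's scores for endothelial, macrophage and skeletal muscle markers were -1.701, -2.002 and -2.216. The other 3 cirmtuzumab libraries averaged -0.14, 0.24 and 0.13 on those lists.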

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

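The test on transcript length and GC content in the outlying library was set before its result was seen, and the other tests in this part were chosen after the results were seen. Single values far from the other 3 libraries of their group were sought in 292 groups of 4 values. There were 38, of which 17 were in control and 21 in cirmtuzumab libraries, and chance gives about 15 for values not chosen beforehand. Most of the genes were chosen by small unadjusted p, the list scores contain many of them, and many flags come from the same library. The flags are therefore not independent, and 38 against 15 is not a test of an excess.

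Among measures of whole libraries, 1 cirmtuzumab library had 104 genes at 0 against 18 to 25 in the others, and a median correlation with the other libraries of 0.877 against 0.972 to 0.977. In the cirmtuzumab group a list score far from the rest was seen for fibroblast (-0.969), endothelial (-1.701), macrophage and myeloid (-2.002) and skeletal muscle markers (-2.216), and for interferon (-0.694) and hypoxia response genes (-0.5). The hypoxia score was that of cirmtuzumab D, and the others were those of the outlying library. In the control group it was seen for Wnt5a/ROR pathway genes (-0.136, control A) and glycolysis enzymes (0.167, control C).

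Single genes with 1 cirmtuzumab library far below the other 3 were NXPE3 at 3.66 log2 CPM, DCHS1 at 4.30, TSPAN8 at -0.50, DSC3 at 4.59, TP63 at -3.06, COL17A1 at 1.62, HSPE1 at 7.34, TIE1 at -1.84, TEK at -1.71, MRC1 at -3.91 and CKM at -0.56. KDM3A at 7.11 and AC092849.2 at 0.39 were far above. The library was the outlying one for all of these genes except HSPE1 and KDM3A (cirmtuzumab C). In the control group 1 library was far below the other 3 for QPRT at 5.81 log2 CPM, SCRIB at 6.21, DOCK5 at 4.46, CBX2 at 4.16, NOTCH1 at 3.42, CLDN3 at 3.62, CDT1 at 4.17, FDXR at 2.73, PFKL at 7.05, SDF2L1 at 3.46, RPS15 at 6.43, KLF2 at -1.07 and EMCN at 0.86. The low library was control A for all of these genes except DOCK5 (control C) and EMCN (control B). Control A also lay at 42.9 on the second principal component, with cirmtuzumab B at the other end at -41.9. ZEB2 at 1.88 (control B) and PGAM1 at 7.85 (control C) were far above.

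The outlying cirmtuzumab library had 820 genes over 2 log2 units below and 169 above the mean of the other 7. Lower depth is excluded, since 4 of the other 7 libraries had lower totals, and so is a trend with transcript length and GC content, which took 0.0765% of the variance of its deviations against 0.672% to 26.2% in the others. Fewer reads from other cell types stay open for the lower genes, since 5 of 5 marker lists (fibroblast, endothelial, macrophage, adipocyte and skeletal muscle) had scores below each of the other 7 libraries, while 5 of their 27 markers lay above each of them. They are excluded for the 169 higher genes, against at most 42 in another library. DSC3 and COL17A1, of the basal keratinocyte-type list, were also far lower in the outlying library, at 4.59 and 1.62 log2 CPM. In the other 7 libraries they lay at 7.92 and 4.83 or above. The score of their list in the outlying library was 0.174, within the others' range of -0.283 to 0.292. Whether fewer reads from other cell types account for such genes was not examined. The origin of that library's cells was not examined, and a difference between tumours stays open and untested.

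For the shifts of 11 gene lists, a trend with transcript length and GC content is argued against as the whole cause, since 9 of 11 kept their calls after adjustment, with YAP/TAZ targets going from -0.35 to -0.27 relative to all genes. It stays open for Hippo components (-0.08 to -0.05 relative to all genes, SE over members 0.0466 and 0.0417, adjusted p = 0.558) and histone genes (0.30 to 0.25, SE over members 0.0762 and 0.0719, adjusted p = 0.232), whose calls ended while their medians did not reach 0. The SE over members is that of a mean over genes taken as independent, and it does not measure the change between fits. The outlying library is argued against as the whole cause of the calls at the preset correlation, since 10 of 11 lists kept them without it. The YAP/TAZ median went to -0.21 and the mesenchymal one to -0.17. That library stays open for fibroblast markers, at -0.22 without it (SE over members 0.114, and 0.128 with it). At the preset correlation other splits of the libraries gave a median of 6 lists and at most 10, and no list passed with an estimated one. A kept call in these tests shows only that the call does not rest wholly on what was tested. A trend with the mean of the fibroblast markers, which are read as human genes and do not measure a share of mouse fibroblasts, is argued against as the cause of all the shifts, since with that mean as a covariate 8 of 10 other lists kept their calls. For YAP/TAZ targets (-0.35 to -0.12, SE over members 0.0792 and 0.0676) and mesenchymal genes (-0.34 to -0.07, SE 0.118 and 0.0943) it stays open, since the fibroblast mean did not separate the groups (difference -0.448, exact permutation p = 0.143), as does an effect of the antibody.

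For GATD3, reads moved between near-identical copies stay open: both copies summed differed by 0.35 (SE 0.133; adjusted p = 0.753), but a rise of GATD3 alone would move the sum by 0.13, less than that error, so the sum decides nothing. GATD3 took 3.94 ± 0.0756% of the counts of both copies in control and 10.8 ± 1.77% in cirmtuzumab tumours (SD, n = 4 each). The outlying library as the source is excluded, since the difference was 1.85 without it. An effect of the antibody on GATD3 stays open.

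Other splits of the 8 libraries into 4 and 4 were fitted the same way, 35 in all. For the genes past the threshold, 1 split had as many, the real one, with 1 gene against at most 0 in another, a share of 0.0286, the smallest that 35 splits can give. The real split had the most genes, but this count sets GATD3 alone against 0, which does not by itself exclude chance. The GATD3 call ended when any 1 of 7 similar libraries was left out. The count of genes without overlap does not exclude chance either, since 10 of 35 splits had as many as the real 542. For the gene lists, 1 split had as many, the real one, with 11 lists against at most 10 in another, and a median of 6, the same share. The real split had the most lists, but a margin of 1 list does not by itself exclude chance. The other tests of the lists do not exclude it either. No list score passed its exact permutation test (smallest adjusted p = 0.497), and no list passed with an estimated correlation (lowest adjusted p = 0.594) or fry (0.451 in one direction and 0.27 in either). At an unadjusted p under 0.05, 9 of 35 splits had as many genes as the real 721, and the highest other had 1600, which points to a structure among the libraries apart from the groups.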

How the results depend on the processing

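The labels' replicate numbers could not be matched to columns, but both groups share 4 numbers in the column names. With these as a replicate block 0 genes passed and the same 11 lists passed, and no other call changed. Deviations from the group means correlated between -0.118 and 0.071 across genes within the 4 pairs, and 2 of 8 libraries correlated best with their own number. The cirmtuzumab mean includes the outlying library, which therefore enters each deviation of that group. These correlations cannot decide whether the shared numbers pair libraries, and that stays open. Another pseudocount was not run because the deposited values are already log2, and camera has no robust variance prior. The settings named last in the methods text were chosen after the data were seen. The 1 changed gene became 0 without the lowest 25% of genes and 0 with GATD3 and GATD3B summed, as the sum is mostly GATD3B and the filter removes GATD3. It became 3 with weights per library (GATD3, SLC6A6 and AC092849.2) and 3 with voom weights and a weight per library (GATD3, AC092849.2 and FP565260.2). Leaving out 1 library gave 0 to 2, with 2 only without the outlying library and 0 without any 1 of the other 7. Counting genes whose groups do not overlap gave 542 (chance 2.86%, observed 3.59%), and 10 of 35 splits had as many. The other 7 settings gave 1. The ROR1 log2 difference ran from -0.82 to -0.01, and from -0.82 to -0.09 when leaving out 1 library; with the deposited symbols it was 0.40, the value of another gene, since those symbols are displaced. The 11 lists became 0 with an estimated correlation, 0 with fry in one direction, 0 with fry in either direction, 0 without the outlying library and with an estimated correlation, and 5 with the deposited symbols. Other settings gave 8 to 12. Basal keratinocyte-type genes reversed to -0.12 without the outlying library (range -0.12 to 0.17 when leaving out 1 library), G2 and mitosis genes to -0.11 with the fibroblast covariate, and histone genes to -0.02 with the deposited symbols. Where not given, the cause was not tested. Of 1901 alternatives for 107 named genes, 1889 left the call as it was, 9 were weaker, 3 stronger and 0 reversed, and of 665 for 29 lists, 577, 81, 4 and 3. A gene or list that stayed uncalled counts as unchanged, so these totals say little about stability. GATD3, the only named gene called, kept its call in 8 of 17 alternatives. Among the 11 called lists the calls kept ran from 7 of 23 (mesenchymal genes) to 19 of 23 (such as DNA replication genes). Among values not called, the sign flipped in 37 alternatives of 30 genes and 65 of 18 lists. Depth may limit genes at low counts such as GATD3, at 109 ± 24.9 expected counts in control tumours (SD, n = 4), which was not tested.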

Other observations

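Gene lists not described above did not pass with camera in the 8 libraries. Epithelial genes had a median difference of 0.03 (adjusted p = 0.942), luminal mammary genes one of 0.05 (adjusted p = 0.644) and basal keratinocyte-type genes one of 0.09 (adjusted p = 0.739). The p53 targets (0.005, adjusted p = 0.627), apoptosis regulators (0.02, adjusted p = 0.732), interferon response genes (0.02, adjusted p = 0.998) and glycolysis enzymes (0.05, adjusted p = 0.726) lay near 0. NF-kB and TNF response genes had a median of -0.11 (adjusted p = 0.607) and immediate early genes one of 0.06 (adjusted p = 0.214). Unfolded protein response genes had a median of -0.004 (adjusted p = 0.922), with a mean of 0.013 and a test in the upward direction. For breast cancer stem cell markers, basal, luminal, p53 and interferon genes the mean was below 0 (-0.072, -0.063, -0.026, -0.002 and -0.188) while the median and the test were above.

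Without the outlying library, a setting planned as 1 of the left-out libraries, NF-kB and TNF response genes (median -0.11, adjusted p = 0.00607) and basal keratinocyte-type genes (median -0.12, adjusted p = 0.032) also passed as lower, and fibroblast markers did not. No list passed there with an estimated correlation (lowest adjusted p = 0.601).

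HBB, the 1 measured erythroid marker, differed by -2.43 (SE 1.02), with an SD of 2.44 among the control libraries.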
